A study of Homo sapiens with 2 samples.

How the data were processed

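RNA of the Ramos B cell line with and without EBV was isolated with the mirVana kit and sequenced from polyA-enriched TruSeq libraries as 125 bp paired-end reads, per the labels' protocols. There was 1 library per condition, 2 in all. The labels give the source as Ramos and the infection state of each sample, which set the groups. A further cell type label names c-Kit-positive spleen cells, which does not describe Ramos and was not used.

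The authors deposited 1 table of 63622 human genes with an FPKM value per library, a locus, a status, a p-value and a q-value, per the file headers. TopHat, Bowtie2, HISAT2 and Cufflinks and the builds GRCh37 and hg19 are named by the submitters' processing notes, with no version or role. The columns are those of a Cuffdiff gene table, per the file headers. How reads shared by genes were divided, the annotation and the scaling between libraries are not given in the sources used here. The p-values and q-values in the deposited table compare the same 2 libraries and were only copied, not recomputed. The deposited log2 fold column is EBV negative over EBV positive in 21410 of 21463 rows with both values above 0, within 0.01, and 1705 of its cells hold a spreadsheet error, so ratios were computed again from the FPKM values. The status was OK in 18785 rows, NOTEST in 44743, FAIL in 72 and HIDATA in 22, and 19 of the HIDATA rows are listed at 0 in both libraries. A 0 in this table can therefore be a failed estimate, and no fold is given against it, although such genes enter the counts through the added 1 FPKM. Loci that start at a counted-from-0 position were written counting from 1, and genes in 1 bundle share 1 locus, whose ends are then those of the whole bundle.

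Values of rows with the same symbol were summed and 7969 rows of small RNA classes were left out, leaving 51042 symbols. The log2 ratio of EBV positive over EBV negative was taken after adding 1 FPKM. Genes at 1 FPKM or more in a library were counted as higher or lower at a log2 ratio of at least 1 or at most -1. No test was made, because the design has 1 library per condition. For each of 30 lists (24 pathways and 6 cell type marker lists, 663 genes, all found, 2 through another symbol), members at 1 FPKM or more in a library were measured. The median ratio of a list with at least 5 measured members was placed among 10000 random lists of the same size drawn from the same 20 bins of mean expression, with the lowest and the highest 2.5% as the bounds. The groups, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 15 highest and 15 lowest genes at 5 FPKM or more, up to 8 members per list with at least a 2-fold ratio (the 3 with the highest mean in a list with none), and a fixed set that includes CR2, FCER2, MYC, MS4A1, CD79A, BCL6, MME and KIT. Some genes that the rule names are not reported here. Further list members named in the report, such as RELB, NFKB2, TNFAIP3, EBI3, CCL22, CCL17, OAS1, IFIT5, XBP1 and IGJ, were chosen after their values were seen.

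FPKM values hold no counts, but values of low genes come in steps of whole fragments. Over 3195 low rows, 56.2% of the ratios between libraries lay within 1% of a ratio of whole numbers once 1 fragment was taken to be worth 1.24 times as much in the EBV-positive library, against 7.64% with a displaced step. With transcript lengths this gives about 114000000 fragments in the EBV-positive and 141000000 in the EBV-negative library, an estimate whose settings were chosen after looking at the values. On 1 kb, counting error alone then gives a log2 ratio without the added 1 FPKM an SE of 0.18 at 1 FPKM and 0.06 at 10 FPKM. With the added 1 FPKM it is smaller, most of all for low genes. It covers neither culture nor library preparation. The SD over genes of the log2 ratio with the added 1 FPKM was 0.41 at a mean of 1 to 10 FPKM, 0.23 at 10 to 100 and 0.15 above.

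The calculation was tested on simulated data for this comparison with 12491 genes and counting error only. It called 98 of 100 genes changed 4-fold, 83 of 100 changed 2.5-fold and 0 of 12291 unchanged genes, and put 5 of 100 unchanged lists beyond the bounds. All simulated genes had the same length and both libraries the same depth, so short genes were not covered. Counting error at these settings is far under 2-fold, so the 0 is no rate of false calls in the real libraries. The alternatives were pseudocounts of 0.1 and 5, no minimum and a minimum of 5 FPKM, a median ratio set to 0, trimmed-mean factors, the highest row per symbol, small RNAs kept and rows of status OK only. Gene types, transcript lengths and GC content came from GENCODE 29 by Ensembl identifier, and no coordinate was taken from it, since its build differs. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.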

Results

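Ramos is a B cell line derived from a Burkitt lymphoma, and Epstein-Barr virus (EBV) is a herpesvirus that persists in B cells. PolyA-enriched RNA of Ramos cells was sequenced with EBV infection and without it, 1 library per condition, to find host genes whose expression goes with infection. The values are FPKM (fragment numbers scaled to transcript length and library size) of 63622 annotated human genes, and 0 rows of the table carry the name of a viral gene or contig. The low values put about 114000000 fragments behind the EBV-positive library and about 141000000 behind the EBV-negative library. With and without EBV refer to the libraries so labelled, and every direction and ranking below would turn if the labels were exchanged, which 0 viral rows leave unchecked. With 1 library per condition no difference has a replicate check, so every value below describes these 2 libraries. Ratios are EBV positive over EBV negative, on the log2(FPKM + 1) scale, which understates the difference of low genes.

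In the EBV-positive library, genes of DNA replication and mitosis were slightly higher, and genes of B cell activation, NF-kB signalling, the interferon response, plasma cells and the unfolded protein response were lower. Large differences were few. Among 12491 genes at 1 FPKM or more in a library, 96 were at least 2-fold higher with EBV and 123 at least 2-fold lower, 1.75% of the genes. TBC1D4, a Rab GTPase-activating protein that regulates glucose transporter traffic, stood at 89.8 FPKM with EBV and 20.3 without. S100A4, a calcium-binding protein, stood at 0.718 FPKM with EBV and 22.7 without, and CD58, the ligand of the T cell adhesion receptor CD2, at 3.36 and 20.2.

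Of the 96 higher genes, 53 reached 5 FPKM in a library and 14 were at least 4-fold higher. Of the 123 lower genes, 56 reached 5 FPKM and 25 were at least 4-fold lower. The counts include 12 higher and 14 lower genes listed at 0 in one library, which pass through the added 1 FPKM and have no fold. Protein-coding genes made up 73 of the 92 higher genes and 95 of the 120 lower genes that have a type in the annotation. Of 1058 genes with a mean of 100 FPKM or more and no failed estimate, 0 were among them. The log2 values of both libraries correlated across 12488 genes with a Pearson r of 0.987, genes not being independent replicates. The median log2 ratio of all 12491 genes was 0.09. Scaling by trimmed means used a log2 shift of 0.11, applied before the added 1 FPKM, so that low genes moved by less. It brought the median to -0.01. Directions of small differences are therefore given relative to the median of all genes.

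**Figure D1:**
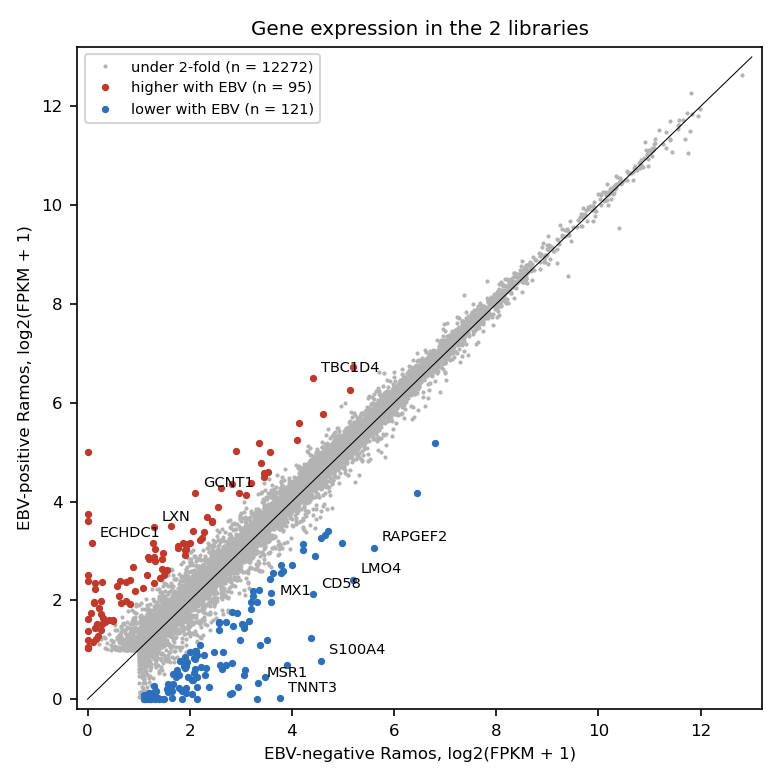
Each point is 1 gene, with log2(FPKM + 1) in the EBV-negative library on the x axis and in the EBV-positive library on the y axis, and the line marks equal values. Red points are the 95 genes at least 2-fold higher with EBV and blue points the 121 at least 2-fold lower, without the 3 genes whose estimate failed in a library, and TBC1D4 and S100A4 lie far from the line on opposite sides.

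Among the genes ranked highest by ratio, ECHDC1, which encodes a metabolite repair enzyme, had 7.90 FPKM with EBV and 0.0591 without (log2 ratio 3.07). ECHDC1 (ENSG00000093144) lies on chromosome 6 from 127609855 to 127664754 in the build named by the submitters, GRCh37. TBC1D4 (ENSG00000136111, chromosome 13, 75858808 to 76056250) had a log2 ratio of 2.09. LXN, a carboxypeptidase inhibitor, had 10.2 FPKM with EBV and 1.45 without, and GCNT1, a glycosyltransferase that branches O-glycans, had 16.9 and 3.29. C2orf88 had 35.4 and 9.19 FPKM, and the Cdc42 effector CDC42EP3 5.40 and 0.855. The adhesion glycoprotein gene CD99 and SDR42E1 and XKRX had log2 ratios of 1.89, 1.72 and 1.69. AL590762.1 and AL358113.1, which share a locus with other genes, had log2 ratios of 2.13 and 1.87. The pseudogenes TAF9P3 and IGLVI-20 had 30.9 and 12.4 FPKM with EBV and AC015987.2, which shares a locus with other genes, 11.3, and all 3 were listed at 0 without it. EEF1A1P5, a near copy of EEF1A1, was also listed at 0 without EBV, but the authors' deposited table gives it the status HIDATA, the mark for a locus with too many fragments to estimate.

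Among the genes ranked lowest, S100A4 (ENSG00000196154, chromosome 1, 153516089 to 153522612) had a log2 ratio of -3.79. TNNT3, a fast skeletal muscle troponin T, had 0.0187 FPKM with EBV and 12.5 without. TIMD4, a phosphatidylserine receptor, had 0.621 and 14.1 FPKM, and the scavenger receptor MSR1 0.247 and 9.12. The interferon-induced membrane protein gene IFITM1 had 0.375 and 10.1 FPKM, and the inflammatory caspase CASP1 0.0823 and 5.87. LMO4, a LIM-domain transcription cofactor, had 4.34 FPKM with EBV and 35.5 without, and RAPGEF2, an exchange factor for Rap GTPases, had 7.40 and 47.5. The protease BACE2, the guanylate cyclase subunit GUCY1B3, the long non-coding RNA LINC00478 and C7orf72 had log2 ratios of -2.70, -2.58, -2.70 and -3.13. AL109927.1 was listed at 0 with EBV and had 8.93 FPKM without. MT-ND4 and MT-ND4L were listed at 0 with EBV, again with the status HIDATA in the authors' deposited table. Of the 219 genes in both directions, 59 higher and 81 lower ones share a locus with another gene, S100A4, TBC1D4, TNNT3, MSR1 and RAPGEF2 among them, and whether reads of such genes overlap was not examined.

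In the authors' deposited table, 80 genes were called significant, 22 higher and 58 lower with EBV. Their q-values in the authors' deposited table ran from 0.0158 to 0.0459, and 45 of the 80 were among the 219 genes, 15 higher and 30 lower. ECHDC1, TBC1D4, MSR1, LMO4, BACE2, LINC00478, CASP1 and GUCY1B3 had a q-value of 0.0158 in the authors' deposited table. CD58, TNFAIP2 and GCNT1 had 0.0459 there and S100A4 0.0536, all from the authors' deposited table. Other genes named here were far from significance in the authors' deposited table, such as C7orf72 (0.561), C2orf88 (0.656), CD86 (0.745) and EGLN3 (0.808), and LXN, AL590762.1, IFITM1 and FAS had 0.9995. Of the 80 genes in the authors' deposited table, 33 were under 1 FPKM in both libraries and 32 were listed at 0 in one. These q-values compare 1 library with 1 library.

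Targets of the viral protein EBNA2 and of Notch, both through the DNA-binding protein RBPJ, were low as a group in the library labelled EBV positive. The list joins both kinds of target, with HES1, DTX1 and NOTCH2 among its measured members, so it is no readout of EBNA2 alone. Of 12 measured members, 8 were below the median of all genes, 2 were at least 2-fold lower and 0 were 2-fold higher. The 2 were CD58 (ENSG00000116815, chromosome 1, 117057157 to 117113661; log2 ratio -2.29) and SLAMF1, a lymphocyte adhesion receptor (1.72 FPKM with EBV, 7.38 without). CR2, the receptor EBV uses to enter B cells, had 5.24 and 6.79 FPKM, FCER2, the classical EBV-induced antigen CD23, 0.259 and 1.11, and MYC 231 and 209. The median log2 ratio of the list was -0.18, at percentile 0.02 among 10000 random lists matched on expression.

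Targets of NF-kB and of the viral protein LMP1, which activates NF-kB, were lower too. Of 21 measured members, 18 were below the median of all genes and 1 was at least 2-fold lower, TNFAIP2 (1.15 FPKM with EBV, 9.41 without). RELB and NFKB2, subunits of the noncanonical pathway, had 28.3 and 45.0 FPKM and 29.8 and 41.2 FPKM, and the inhibitor TNFAIP3 had 6.56 and 12.2. The list median was -0.19, below those of all 10000 matched random lists. EBI3, CCL22 and CCL17, chemokine and cytokine genes induced by LMP1, were under 1 FPKM in both libraries.

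Activation and adhesion molecules had 13 of 19 measured members below the median of all genes, and those at least 2-fold lower included CD58 and FAS (2.94 FPKM with EBV, 8.15 without). CD86, a costimulatory ligand, was the 1 member at least 2-fold higher, with 7.58 FPKM with EBV and 2.43 without. The list median of -0.10 lay at percentile 0.01. Among 14 measured chemokine, cytokine and receptor genes, CCR10 (2.34 and 6.61 FPKM) and IL7R (1.97 and 4.95 FPKM) were at least 2-fold lower and 10 were below the median of all genes. Their median of -0.19 was below those of all random lists.

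Interferon-stimulated genes were low in the EBV-positive library. Of the 38 genes of the list, 16 were under 1 FPKM in both libraries. Of 22 measured members, 18 were below the median of all genes. MX1 (2.93 FPKM with EBV, 11.1 without), PARP14 (0.776 and 3.26) and EPSTI1 (0.0650 and 1.16) were at least 2-fold lower. IFI44, listed at 0 with EBV and at 1.38 FPKM without, is counted with them on the scale used but has no fold. The 4 members above the median of all genes were OAS1, with 48.7 and 34.1 FPKM, STAT2 (62.0 and 45.7), OAS2 (22.7 and 20.1) and IFIT5 (2.47 and 1.28). The list median of -0.18 was below those of all random lists. MHC class I genes had 17 of 20 members below the median of all genes, none of them 2-fold lower. HLA-B had 356 FPKM with EBV and 415 without, B2M 1456 and 1633, and CALR 590 and 598, and the list median of -0.04 lay at percentile 0.04.

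Plasma cell genes had the lowest list median in the library labelled EBV positive, -0.36, below those of all random lists, with 11 of 12 measured members below the median of all genes. SLAMF7 was at least 2-fold lower (0.364 FPKM with EBV, 2.90 without). TNFRSF17 (39.9 and 29.1 FPKM) was the 1 measured member above the median of all genes. PRDM1 and SDC1 were under 1 FPKM in both libraries and do not enter the list median. The secretory transcription factor XBP1 had 191 and 244 FPKM and the immunoglobulin joining chain, IGJ in the table, 2165 and 2785. The unfolded protein response list, which shares XBP1 and HERPUD1 with the plasma cell list, had 22 of 23 members below the median of all genes and 0 at 2-fold. Its median of -0.09 was below those of all random lists. The chaperone HSPA5 had 239 and 254 FPKM, ATF4 626 and 593 and ASNS 346 and 336. ATF4 and ASNS (log2 ratios 0.08 and 0.04) were also below the median of all genes, and DDIT3 (0.16) was the 1 member above it.

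Glycolysis and hypoxia genes had 26 of 28 measured members below the median of all genes. The oxygen sensor EGLN3 (0.508 FPKM with EBV, 7.51 without) and the enolase ENO2 (1.79 and 6.20) were at least 2-fold lower, and the list median of -0.07 was below those of all random lists. Oxidative phosphorylation genes had a median of 0.02 at percentile 0.77, with 22 of 32 below the median of all genes and ATP5A1 (673 and 620 FPKM), ATP5B (653 and 622) and COX4I1 (460 and 490) as the members with the highest means. All of these were under 2-fold.

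DNA replication genes were the highest list in the library labelled EBV positive, with 23 of 24 members above the median of all genes and none 2-fold higher. The helicase subunit MCM7 had 435 FPKM with EBV and 355 without, PCNA 439 and 388, and the thymidylate synthase TYMS 311 and 290. The median log2 ratio was 0.21 at percentile 99.97. Genes of mitosis and proliferation had 21 of 24 members above the median of all genes, a median of 0.18 and a percentile of 99.5. UBE2C had 246 and 204 FPKM and CCNB1 207 and 175, while NUSAP1 had 193 and 213.

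**Figure D2:**
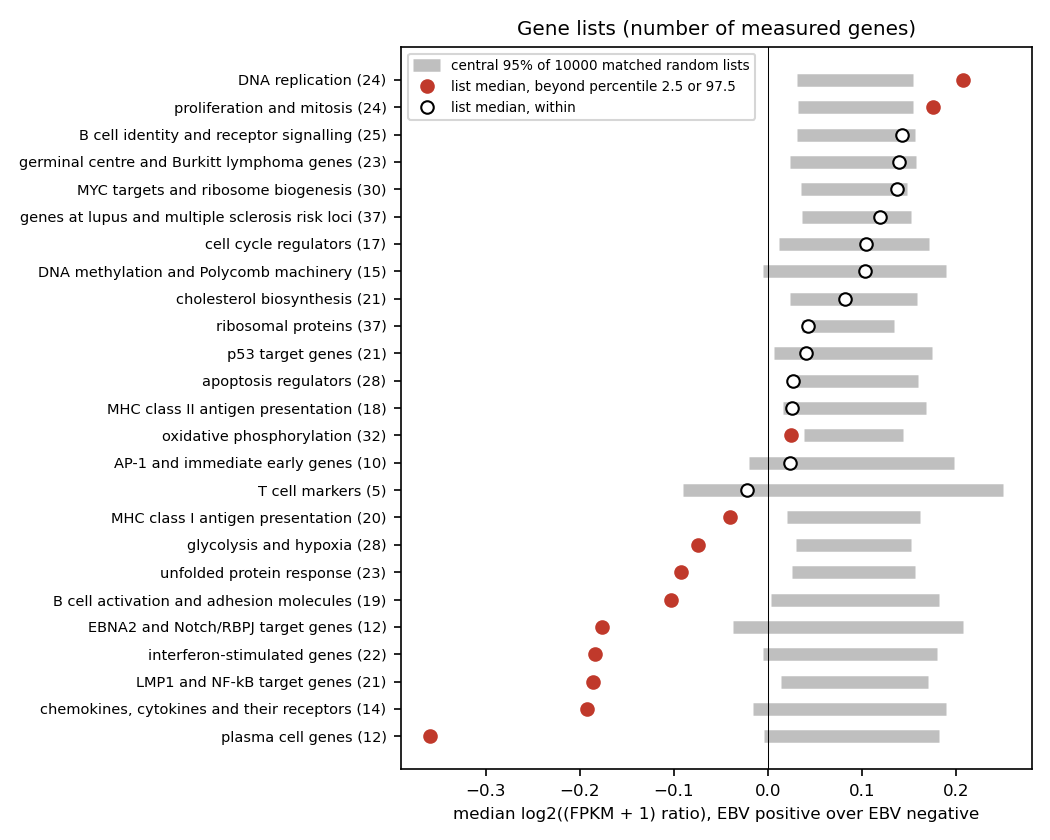
Each row is 1 gene list with its number of measured genes, the point is the median log2((FPKM + 1) ratio) of EBV positive over EBV negative on the x axis, and the grey bar spans the central 95% of 10000 random lists matched on expression. The plasma cell list lies farthest left at -0.36 and the DNA replication list farthest right at 0.21.

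B cell identity genes lay within the range of the random lists, at percentile 93.9, with 18 of 25 above the median of all genes. CD79A had 552 FPKM with EBV and 507 without, CD79B 451 and 405, CD22 354 and 361, and MS4A1, the gene of CD20, 351 and 226. Germinal centre and Burkitt lymphoma genes were at percentile 91.7, with 17 of 23 above the median of all genes. BCL6 had 202 and 159 FPKM, MME, the gene of CD10, 187 and 167, TCL1A 964 and 886, TCF3 501 and 459, and ID3 449 and 415. MHC class II genes were at percentile 4.07 (1.91 with no minimum) and apoptosis regulators at 3.32 (2.44 with trimmed-mean scaling), with FAS as the 1 apoptosis member at least 2-fold lower. CD74, HLA-DRA and HLA-DPA1, the MHC class II members with the highest means, had log2 ratios of -0.02, -0.08 and 0.01.

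Among genes at lupus and multiple sclerosis risk loci, 21 of 37 were above the median of all genes and the list was at percentile 80.2. ZMIZ1, a transcriptional coregulator, was at least 2-fold higher (30.9 FPKM with EBV, 10.9 without), as was CD86, and CD58 and IL7R were at least 2-fold lower. The p53 targets were at percentile 11.8 (up to 20.9 under the alternatives), with CDKN1A (0.524 and 3.28 FPKM) and FAS at least 2-fold lower. Cell cycle regulators, which also hold CDKN1A, were at percentile 61.9. MYC targets and ribosome biogenesis genes were at percentile 94.1 (NPM1 3309 and 2698 FPKM, NCL 1223 and 1086, LDHA 2581 and 2685), and ribosomal proteins at 3.93, up to 6.32 under the alternatives (RPS24 3709 and 3401 FPKM, RPS18 3402 and 3232, RPS23 3162 and 3069). Cholesterol biosynthesis genes were at percentile 37.7 (FDFT1 378 and 375 FPKM, FDPS 340 and 332, INSIG1 206.2 in both). DNA methylation and Polycomb genes were at 56.8 (up to 90.5 under the alternatives), DNMT1 having 195 and 149 FPKM, EZH2 108 and 85.0 and HDAC1 140 and 131, and AP-1 and immediate early genes were at 11.1, with 0.15 under no minimum and up to 19.6 otherwise (JUND 35.7 and 35.5 FPKM, IER2 29.1 and 28.3, ZFP36L1 27.1 and 25.9).

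**Figure D3:**
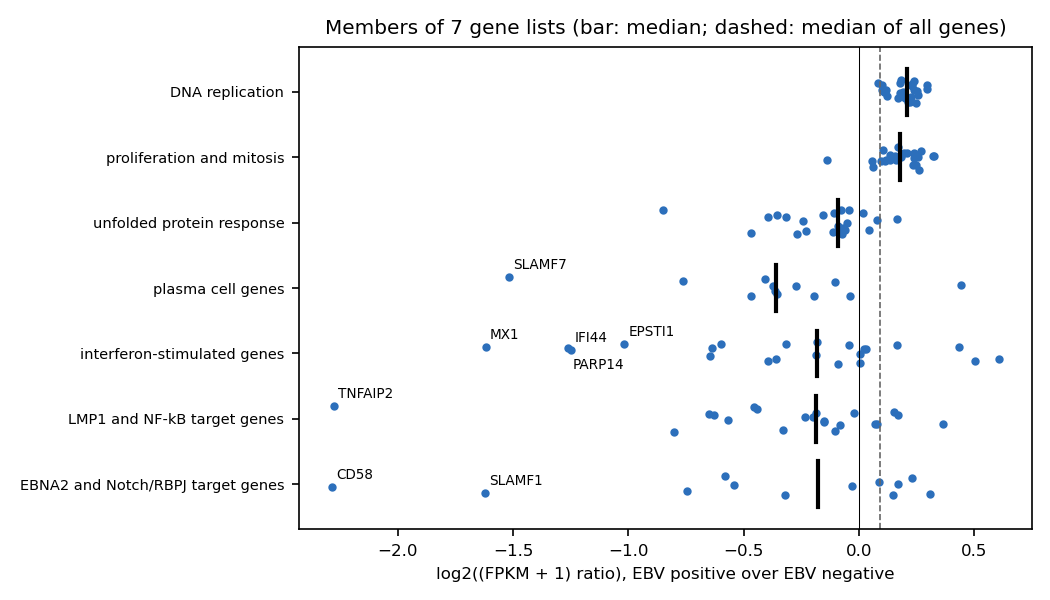
Each point is 1 measured gene of 7 lists, its log2((FPKM + 1) ratio) of EBV positive over EBV negative on the x axis, spread vertically at random for legibility. Black bars are list medians and the dashed line is the median of all genes, which 23 of 24 DNA replication genes exceed and under which 18 of 21 NF-kB and LMP1 targets lie.

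Of 78 markers of other cell types, 8 reached 1 FPKM in a library, 31 had lower values and 39 were listed at 0 in both, all 39 with the status NOTEST and 0 with HIDATA or FAIL. The T cell list had 5 measured members, TRBC2 at 186 FPKM with EBV and 193 without, LCK at 163 and 177 and TRAC at 84.0 and 83.7 having the highest means, and lay at percentile 10.8 (up to 18.7 under the alternatives). Each of the other 5 marker lists had under 5 measured members. Natural killer cell markers and fibroblast and epithelial markers had 0 genes at 1 FPKM. The monocyte and macrophage list had AIF1 (11.9 FPKM with EBV, 4.06 without), the progenitor list LMO2 (6.19 and 9.97) and the erythroid list EPOR (7.05 and 7.92). KIT was listed at 0 in both libraries, although a cell type label of both samples names c-Kit-positive spleen cells.

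Of the 25 lists with at least 5 measured members, 10 were in the lowest 2.5% of the random lists and 2 in the highest 2.5%. By chance 1.25 would lie beyond the bounds if the genes within a list varied independently of one another. The lists share genes, genes of a pathway vary together, and the percentiles describe these 2 libraries rather than the effect of infection.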

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

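All alternatives in this part were fixed before the data were examined, and a named gene was taken to have moved when its ratio differed by more than 1.5 times, a bound set because there are no replicates. The counts of 96 higher and 123 lower genes became 190 and 227 with a pseudocount of 0.1, 20 and 27 with a pseudocount of 5, and 53 and 56 with a minimum of 5 FPKM, by construction, since the pseudocount and the minimum act on low genes. They kept within 1.5 times under the other 6 alternatives. Of called genes, 43.8% were higher as deposited, 37.9% (86 against 141) with the median ratio set to 0 and 37.3% (85 against 143) with trimmed-mean factors; exchanged library names would turn the first share into 56.2%. Of 224 values for lists, 221 stayed on the same side of the bounds, all those of the 12 lists beyond them included. MHC class II genes came to percentile 1.91 and AP-1 genes to 0.15 with no minimum, and apoptosis regulators to 2.44 with trimmed-mean factors; the cause was not tested. Of 896 values for named genes, 66 moved, all with a changed pseudocount, and 0 reversed. T cell markers had under 5 genes at 5 FPKM, and EEF1A1P5, KIT, MT-ND4 and MT-ND4L have no row of status OK, so these have no value there. Depth limits low genes: at 1 FPKM on 1 kb, counting error is 0.18 for a log2 ratio without the added 1 FPKM, and smaller with it.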

Other observations

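The families in this paragraph and all tests below except that of expression level were chosen after the values were seen; the 3 lists of the first pattern were also picked after seeing that 10 lists were low. S100 and annexin genes, which bind calcium and membranes, were lower in the EBV-positive library for S100A4, S100A6 (0.0356 FPKM with EBV, 1.21 without), ANXA2 (35.6 and 110.2) and ANXA6 (1.96 and 5.51), while ANXA11 had 125 and 122. ANXA2 and S100A4 share a locus with another gene. Within the SLAM family of lymphocyte receptors, SLAMF1 and SLAMF7 were at least 2-fold lower. Members under 2-fold on the log2(FPKM + 1) scale had 3.74 and 7.93 (LY9, log2 ratio -0.92), 87.2 and 129 (CD48) and 60.7 and 60.3 (SLAMF6). The inflammatory caspase relatives CASP1 and CARD16 (0.120 and 2.62) were lower, with CASP4 at 2.71 and 2.77. CASP1 also shares a locus with other genes, and whether it shares reads with CARD16 was not examined.

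Among integrins, ITGB1 was higher with EBV at 47.1 FPKM against 16.6, while ITGA4 had 22.0 and 20.4 and ITGB7 53.2 and 66.3. Among immunoglobulin constant genes, IGLC2 (9.54 and 25.3), whose reads can be shared with IGLC3, was at least 2-fold lower, while IGHM (2582 and 3301), IGLC3 (2895 and 3529) and IGHD (22.3 and 39.0) were under 2-fold. IGHG3 had 2.96 FPKM with EBV and 0.194 without.

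EBNA2 and Notch/RBPJ targets, LMP1 and NF-kB targets and interferon-stimulated genes lay low in the library labelled EBV positive, 54 genes together with a median of -0.18, 7 of them at 2-fold or more. For the 54 genes together, low genes alone do not account for it. The 31 members at 10 FPKM or more had a median of -0.08, percentile 0 among matched random lists. Genes matched on GC content, length and expression had a median of 0.09. Genes of like GC content and length were thus not lowered in general. That the 54 genes lay at percentile 0 among 10000 such matched lists adds no support. The 54 genes come from lists chosen as low on the same ratios. GC content and length took 0.258% of the variance of the ratios. Neither test was run on each list alone. Of EBNA2 and Notch/RBPJ targets at 10 FPKM or more, FGR (log2 ratio -0.58) and CD58 (-2.29) were low. RUNX3 (0.09), MYC (0.15) and DTX1 (0.23) lay near or above the median of all genes, so low genes stay open for that list. Exchanged column names may account for the low lists. The 7 genes that EBV latency proteins lower elsewhere (IGHM, CD79B, TCL1A, BCL6, MME, MYBL1, CD38) lay at percentile 81.9, too near the middle to decide, and there are no viral rows to check the labels. That reading takes EBNA2 and LMP1 to be made in the infected cells, which the absence of viral rows leaves unknown. Also open and untested is divergence of separately kept sublines. Infection and library cannot be told apart with 1 library each.

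MSR1 and TIMD4, known from macrophages, were among the lowest genes with EBV, which raises macrophages in the EBV-negative culture as a candidate source. The 13 monocyte and macrophage markers other than AIF1, which was left out after its values in both libraries were seen, summed to 0.301 FPKM in the EBV-negative library, against 9.12 for MSR1 alone. Of the 13, 6 are listed at 0 there and 7 are not, CD14 at 0.0863, MS4A7 at 0.0851 and CD68 at 0.0388, and 0 have the status HIDATA or FAIL. That is too little for macrophages to bring the MSR1 reads. Expression by the Ramos cells themselves, differing with EBV or between sublines, is a hypothesis that these data leave untested.

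For 341 chromosome windows of 5 Mb with at least 10 genes at 5 FPKM or more, the deviation of the window median was multiplied by the square root of the gene number. A window with many genes thus passes at a smaller deviation. In 5 windows the product lay beyond the 95th percentile of the largest product over 2000 shufflings of genes within expression bins. These were chromosome 13 from 40 to 45 Mb, chromosome 6 from 5 to 10, 20 to 25 and 30 to 35 Mb, and chromosome 7 from 125 to 130 Mb, all higher with EBV. Genes elsewhere matched on GC content, length and expression had medians of 0.09 to 0.10, near the 0.10 of all genes in windows. Genes of like GC content and length were thus not raised elsewhere. That 5 of the 5 windows lay above their matched lists adds no support. The windows were chosen as extremes of the same ratios, and GC content and length took 0.258% of the variance of the ratios. Of windows with 5 or more unshared genes, 3 of 3 kept at least 50 percent of their deviation without genes that share a locus, against 1 of the 2 with fewer, so that shared reads stay open there (the other, 6 from 5 to 10 Mb, had -0.01 from 3 genes). From 0 to 40 Mb on chromosome 6, a span chosen from the data, 164 of 227 genes (72.2%) were above the median with a median of 0.21, against 0.09 for 151 genes on the rest of the chromosome. A copy number difference between the sublines is a candidate explanation, for which no DNA was analysed here. The sizes of the shifts were not compared with that of a copy gain. From 30 to 35 Mb on chromosome 6 the deviation was 0.13, with 84 of 114 genes above the median. HLA-B (log2 ratio -0.22) and HLA-DRA (-0.08) there were below it. Both sum several rows, and the windows were not recomputed with 1 row per symbol. Rolling medians, chromosome medians and neighbouring 2-fold genes were also looked at and not tested.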
